A study of Rattus norvegicus with 24 samples.

How the data were processed

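RNA of cortical microvessels of 24 rat samples was hybridised to 1 array each, 8 in each of 3 groups taken from the labels. Per the submitters' processing notes the values were made with RMA, which gives normalised log2 signals. Its version is not given in the sources used here. Per the labels' protocols single-stranded DNA was labelled with an Affymetrix kit for whole-transcript arrays, while the probe identifiers and the platform annotation are those of an Affymetrix 3' expression array, and this mismatch was not resolved.

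The deposited table, as provided here, does not hold the log2 values themselves. Its 746376 cells are whole numbers of at most 9 digits, and 0 end in the digit 0. The first digits of 9-digit cells are nearly even, with shares of 10.7% to 11.3%. The cells were taken as the decimals of log2 values of 10 significant digits, without the integer part and without leading or trailing zeros. A value below 10 then has 9 decimals and a value from 10 on has 8. Whether this loss lies in the deposit or arose later is unknown. Several features were checked. The decimals of a probe's arrays clustered, with a median resultant length of 0.469 against 0.225 after shuffling. The hybridization controls, added at rising amounts, had on average 20, 13.5, 0 and 0 of 24 cells of 9 digits for bioB, bioC, bioD and cre. Of 53 ribosomal protein probes 58.5% lay at 10 or above on all arrays, against 6.22% of all probes.

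Probes with 1 to 14 cells of 9 digits were called near 10. A probe below 10 on all arrays has 14 or fewer with a chance of 0.00878 if zeros are lost independently between arrays. As the decimals of a probe cluster, a probe whose first decimal is often 0 can enter the range more often. Some probes called near 10 may thus lie well below it. In all probes called near 10 a cell of 9 digits was read as 9 plus its decimals and a cell of 8 digits as 10 plus its decimals. Shorter cells were missing, 14.2% of readings. A value below 10 whose first or last decimal is 0 also has 8 digits and is then read too high.

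The reading and its range were chosen after the table was seen and after the calls of other readings were known. The others were a reading of the decimals as angles around a circle, in 2 versions and at 4 limits, and an undirected test of angles. A model of each probe over dropped zeros and over integer parts in a limited range around 10 was also tried. The first version of that model was wrong, because it gave values of 9 and 8 decimals equal weight although the grid of 9 decimals is 10 times finer. The corrected version was kept as an alternative. The choice was then tested on simulated data, with log2 values of 14218 genes encoded to digits as above and read back. In HAL 200 of them were changed, all of a level within 1 of 10. Changes of genes at lower levels, which can enter the range through lost zeros, were not simulated, so their direction was not tested. On the 1072 simulated genes near 10, 84 were changed in HAL minus Sham, and the reading used here called 42 of them, 0 in the wrong direction, and 0 unchanged genes. It recovered 31.6%, 54.5% and 56.2% of the changes of 0.5, 1 and 2 on the log2 scale, with a median read size of 1.22, 0.815 and 0.434 times the true one. Undamaged values gave 81 of 84. The corrected model called 33, 0 in the wrong direction, and 1 unchanged gene. The first version called 17, of which 6 in the wrong direction.

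Of 31099 probes 20832 had 1 gene symbol, 436 several and 9831 none in the platform annotation. Of the former, 20764 had an Entrez identifier in the rat gene table of assembly GRCr8, used for names only, and 0 symbols changed. Each gene was represented by its near-10 probe of the highest mean reading. Genes can have other probes, outside the range, that were not read. Of the called genes with at least 2 probes near 10, 1 of 6 in HAL (Adamts9) and 1 of 8 in HEP (B4galt5) had a probe of the other sign. A gene needed 2 readings in each group, which left out 1. No columns were identical. Across probes near 10, the readings of pairs of arrays of the same group correlated with a median of 0.175 (-0.0187 to 0.314). Replicate arrays thus agreed only weakly on these readings. limma 3.58.1 in R 4.3.3 was fitted with group means over all 24 arrays and eBayes without trend, with Benjamini-Hochberg adjustment over 1738 genes. The planned filter on dim probes needs levels and could not be used. The test itself was kept as planned for log2 values. camera was run on lists of at least 5 members, with missing readings set to the group mean. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for reading the digits.

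The 26 functional lists and 13 cell type lists, the tests and the rule for named genes were fixed before the data were examined. By that rule the text names genes from the 8 largest rises and 8 largest falls among called genes whose arrays all lie on that side of the Sham mean, up to 3 called members of each list or else the one with the smallest p, and 12 preset genes. Ell, Atp10a, Mpdz and Tpm1 were named after their values were seen. Alternatives included array centring, the mean of probes, trend and robust eBayes, array weights, only the groups compared, a block for the sample number, all probes, other set tests, and each array left out in turn.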

Results

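Gene expression was measured in microvessels isolated from the brain cortex of rats in 3 groups of 8 arrays each. In 2 groups acute liver failure had been induced in 2 steps. A portocaval anastomosis, which leads portal blood past the liver, was followed 24 h later by ligation of the hepatic artery (HAL) or by removal of the whole liver (HEP). Sham rats had a fictitious surgery in 2 steps. The rats were killed 8 to 12 h after the last step. The comparisons ask how the vessels of the cortex differ from Sham in each model and whether the models differ from each other. The labels do not say that each array is a separate rat, so p-values measure the spread between arrays, whose number limits the precision.

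The values as provided here hold only the digits after the decimal point of each log2 signal. A level and a direction were read only for probes whose signal was taken to lie close to 10 on the log2 scale, where the number of decimals changes. These were 2527 of 31099 probes, and 1738 genes were tested. The choice rests on the number of digits, so some of these probes may lie below 10 at a level that was not read. A reading is the log2 signal set at 9 or 10 plus its decimals, and differences are between the mean readings of groups. For some genes the number of arrays at 10 or above is given out of the arrays read, which leaves out cells too short to be read. Signals beyond 9 or 11 are misread by at least a whole unit, so a move across these levels can change the size and even the direction of a difference. Signals just above 10 lose a decimal and are not read. In the simulated HAL minus Sham comparison called changes of 0.5 were overstated (median 1.22 times the true size). Those of 1 and 2 were understated (0.815 and 0.434 times). No difference is thus an exact fold. A further 1933 probes had no cell of 9 digits, as a signal of 10 or above on every array gives. Changes of these and of the 26639 probes below 10 are not reported. A model of the integer parts, tried as an alternative, called 60 of these 28572 probes in HAL and 5 in HEP. It covers only integer parts in a limited range around 10, and its directions away from 10 were not tested on simulated data.

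Levels are given for marker genes as a description only, since probes differ in affinity. Of 18 endothelial markers with a probe, 15 had one without a cell of 9 digits on the 24 arrays, taken as a signal of 10 or above on all of them, among them Cldn5, Pecam1, Flt1 and Abcb1a. The same held for 4 of 14 pericyte markers, 4 of 12 smooth muscle markers and 5 of 11 perivascular fibroblast markers. Markers of astrocytes, whose endfeet wrap the vessels, did so in 6 of 15, with Gfap and Gja1 among them, and oligodendrocyte markers in 2 of 14. None of the 18 neuron, 17 microglia, 14 neutrophil and monocyte, 13 lymphocyte, 11 choroid plexus or 14 hepatocyte markers did, but 6 of the neuron markers lay near 10. Of 6 red cell markers 1 did.

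Ptges, the inducible prostaglandin E synthase, had the largest rise in HAL, from a reading of 9.64 ± 0.34 in Sham (SD, n = 7) to 10.77 ± 0.20 in HAL (SD, n = 7), and lay at 10 or above on 1 of 7 Sham and 7 of 7 HAL arrays read. Slc1a1, a glutamate transporter, rose by 0.98, and Adamts9, a matrix protease, by 0.97, the latter at 10 or above on 1 of 8 Sham and 7 of 7 HAL arrays. A second probe of Adamts9 near 10 had a difference of -0.44 in HAL, so the probes of this gene disagreed, and their mean did not pass (difference 0.27, adjusted p = 0.449 in limma). Lama4, a laminin chain of the vascular basement membrane, fell by 0.93, from 7 of 7 Sham arrays at 10 or above to 1 of 7 HAL arrays. Slc38a5, a glutamine transporter of brain endothelium, fell by 0.79, from 7 of 7 arrays to 1 of 8. In limma with Benjamini-Hochberg adjustment 66 of 1738 genes passed an adjusted p of 0.05, 21 higher and 45 lower in HAL, and 5 of them by at least 2-fold in the readings. With each array centred on its median the split was 41 higher and 44 lower. At an unadjusted p under 0.05 there were 307 genes. Without HAL arrays 2 and 5 and Sham array 3, which had the lowest median readings, 37 genes passed, 9 of them by at least 2-fold, and without HAL array 5 alone 8 passed by at least 2-fold. The model-based reading, the range of 3 to 12 cells of 9 digits and short cells read with leading zeros each gave 3 genes of at least 2-fold. Fisher's exact test of the number of cells under 9 digits, unread ones included, called 0 of 6087 genes in HAL and 0 of 6048 in HEP. At its smallest possible p of 0.000155 a single gene could not pass over so many, so the HAL count, with 9 genes at that p, says little. In HEP no gene reached it, with a smallest p of 0.00140 in Fisher's test. That limit thus does not account for the 0 in HEP.

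**Figure D1:**
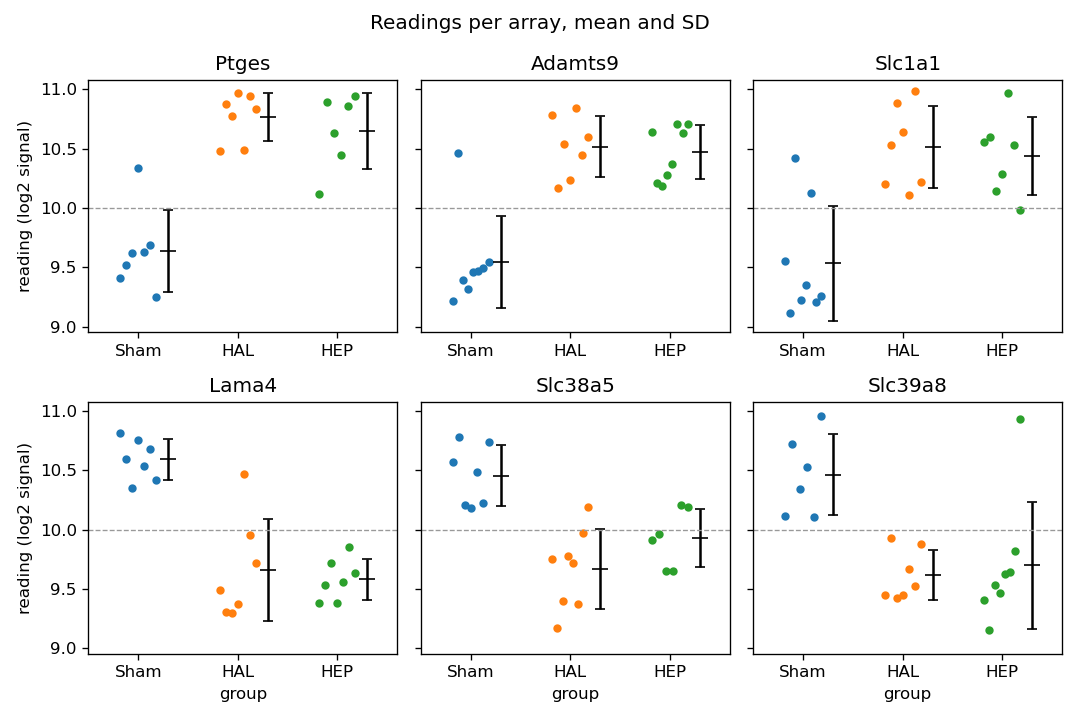
Readings of 6 genes on the log2 scale (vertical axis) in the Sham, HAL and HEP groups (horizontal axis), 1 point per array read, with the mean and SD beside the points and the level of 10 as a dashed line. Ptges, Adamts9 and Slc1a1 lie mostly below 10 in Sham and above it in HAL and HEP, and Lama4, Slc38a5 and Slc39a8 the other way in HAL. Each gene is shown by 1 probe, and another probe of Adamts9 near 10 had a difference of -0.44 in HAL.

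Other genes that rose most in HAL were Fam43a by 0.85 (SE 0.16, adjusted p = 0.00585 in limma), which lay at 10 or above on 0 of 8 Sham and 6 of 7 HAL arrays, and the metallothionein Mt2A by 0.82 (SE 0.19, adjusted p = 0.0153 in limma). B4galt5, Scn4b and Prxl2a rose by 0.78, 0.77 and 0.77. With the mean of its 2 probes near 10, B4galt5 had a difference of 0.37 and did not pass (adjusted p = 0.296 in limma). The largest fall was that of Paqr5, a membrane progestin receptor, with a difference of -1.26 (SE 0.25, adjusted p = 0.00626 in limma) and 5 of 5 Sham against 0 of 8 HAL arrays at 10 or above. Tnfrsf11b, the decoy receptor osteoprotegerin, had a difference of -1.11 (SE 0.20, adjusted p = 0.00385 in limma) and 7 of 7 against 0 of 8 arrays. Tdrp, Stx3, Rgs17, Syne1 and Gpr155 fell with differences of -1.08, -1.003, -0.97, -0.92 and -0.91. For 58 of the 66 genes the number of cells under 9 digits, unread ones included, moved by at least 3 in the direction of the reading. The number of digits also sets the reading, so this is no separate evidence of direction. Of the 68 genes chosen by the rule for names, 24 had another probe below 10 whose change was not read, Ptges and Lama4 among them. A probe at 10 or above on all arrays, also not read, was held by 7: Arid1b, Col1a2, Jam2, Klf6, Nr1d2, Stx3 and Tdrp.

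Of 39 gene lists fixed before the data were examined, 12 had at least 5 tested members, and camera with a preset correlation of 0.01 called 4 of them in HAL, and 0 with an estimated correlation. The Wnt target and barrier programme list, whose genes are known for forming and keeping the barrier, was lower (adjusted p = 0.00818, and 0.0872 with the estimated correlation). Of its 8 tested members 2 passed, or 3 adjusted over the list alone. Tspan12, a co-receptor of Norrin signalling, had a difference of -0.80, and Adgra2, a co-receptor of Wnt7 signalling also called Gpr124, of -0.77. Blood-brain barrier transporters were lower (adjusted p = 0.0270, and 0.0872 with the estimated correlation), with 2 of 10 members passing, or 3 adjusted over the list alone. These were Slc39a8, a zinc and manganese transporter, with a difference of -0.84, and Slc38a5. Glucocorticoid response genes were higher (adjusted p = 0.0270, and 0.0872 with the estimated correlation), with 1 of 7 passing, Mt2A, or 2 adjusted over the list alone. Hypoxia response genes were higher (adjusted p = 0.0286, and 0.0872 with the estimated correlation) with 0 of 5 passing, or 2 adjusted over the list alone, and Higd1a, a mitochondrial hypoxia-induced protein, had a difference of 0.30 (adjusted p = 0.0884). The range of 3 to 12 cells of 9 digits left 2 calls. The Wnt list was called with any 1 of the 16 arrays left out, but the other 3 calls ended without HAL array 6, and those of the transporters and the hypoxia genes also without HAL array 7. The transporter call ended without HAL array 5 as well, and the hypoxia call without Sham array 3.

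Among the lists not called in HAL, the junction genes leaned higher (adjusted p = 0.0587 in camera, and 0.0872 with the estimated correlation), 4 of 5 with positive differences. This list was called without Sham array 7, Sham array 8 or HAL array 8, and reached 0.0993 in camera without HAL array 5. Of the 5 genes 1 passed, Jam2, an endothelial adhesion molecule of tight junctions. It rose by 0.51 with 2 of 8 Sham and 7 of 7 HAL arrays at 10 or above. With the mean of its 2 probes near 10 it rose by 0.36, which did not pass (adjusted p = 0.148 in limma). Of 8 angiogenesis genes 1 passed, Nrp1, a co-receptor of VEGF, with a difference of -0.87. Of 5 oxidative stress genes 2 passed, Mt2A upward and the glutathione transferase Gsta4 with a difference of -0.75. Of 8 clock genes 1 passed, Nr1d2, with a difference of -0.66, but it lay at 10 or above on 7 of 7 Sham and 6 of 8 HAL arrays, so its direction rests on few arrays. Lists of fewer than 5 tested members were described only. In them Col3a1 of the perivascular fibroblasts and Atp13a5 of the pericytes fell with differences of -0.87 and -0.79, and adjusted over the list alone 2 of 2 fibroblast and 1 of 4 pericyte markers passed. Of 4 endothelial markers 1 passed, Slc38a5, which is also among the barrier transporters. Their median difference was -0.33 and 0 of the 4 were positive, and Erg of these also belongs to the Wnt list. None of 3 inflammatory, 3 interferon and 3 acute phase genes passed, or 2 of the acute phase genes adjusted over the list alone, and Lcn2, an acute phase protein of neutrophils and inflamed vessels, had a difference of 0.80 (adjusted p = 0.0919 in limma). None of 6 neuron, 4 astrocyte, 4 oligodendrocyte and 2 microglia markers passed.

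In HEP Ptges rose by 1.01, Adamts9 by 0.92 and Slc1a1 by 0.91, at 10 or above on 6 of 6, 8 of 8 and 6 of 7 HEP arrays read. Depp1, a FOXO target, rose by 0.92 and Wfdc1, a secreted protease inhibitor, by 0.86. Sesn2, a sestrin induced by stress, rose by 0.83, at 10 or above on 2 of 8 Sham, 1 of 7 HAL and 7 of 8 HEP arrays. Lama4 fell with a difference of -1.01 (SE 0.16, adjusted p = 0.00256 in limma) and lay at 10 or above on 7 of 7 Sham and 0 of 7 HEP arrays. In limma 49 genes passed, 28 higher and 21 lower, and 4 by at least 2-fold in the readings. At an unadjusted p under 0.05 there were 277 genes. The count depended on single arrays: it was 113 without HEP array 8, and 30, 29, 29, 23 and 22 without HEP arrays 3, 4, 5, 6 and 7. It was 101 with array weights and 32 in a fit of HEP and Sham alone. The 4 genes of at least 2-fold became 0 without Sham array 1, 2 without Sham array 4 or HEP array 3, and 1 without HEP array 4 or 7. There were 0 in the model-based reading and with short cells read with leading zeros, and 1 in the range of 3 to 12 cells.

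Further falls in HEP were those of Pde6b, Arid1b, Cxxc5, Cachd1 and Dock11, with differences of -1.04, -0.99, -0.86, -0.80 and -0.79. Camera called 3 lists, and 0 with an estimated correlation. Immediate early genes were higher (adjusted p = 0.0355, and 0.0829 with the estimated correlation), with 2 of 5 members passing, Klf6 by 0.65 and Dusp6, a phosphatase that limits ERK signalling, by 0.60, and 2 adjusted over the list alone. Klf6 lay at 10 or above on 7 of 8 Sham and 7 of 7 HEP arrays, so its direction rests on few arrays. For 46 of the 49 genes the number of cells under 9 digits, which also sets the reading, moved by at least 3. Klf6, Nr1d2 and Ell were the exceptions. Hypoxia response genes were higher (adjusted p = 0.0355, and 0.0829 with the estimated correlation), with 1 of 5 passing, Higd1a by 0.43, or 2 adjusted over the list alone. Blood-brain barrier transporters were lower (adjusted p = 0.0355, and 0.170 with the estimated correlation), with 1 of 10 passing, Slc39a8 with a difference of -0.76, or 3 adjusted over the list alone. Slc38a5 had a difference of -0.53 (adjusted p = 0.0901 in limma). With the mean of all near-10 probes of every gene, the differences of Dusp6 and Slc39a8, which have 1 such probe each, were unchanged, but their adjusted p rose to 0.05004 and 0.0516 in limma. No list was called in the model-based reading, in the range of 3 to 12 cells of 9 digits, or with short cells read with leading zeros. No list was called either without Sham array 2, Sham array 4 or HEP array 3, and only the transporters without HEP array 8. The transporter call also ended without Sham arrays 6 and 8 and HEP array 1. In the lists not called, Gsta4 fell with a difference of -0.73, and Nr1d2 had a difference of -0.71 that passed, but it lay at 10 or above on 7 of 7 Sham and 4 of 5 HEP arrays, so its direction rests on few arrays. Mt2A rose by 0.74, and 0 of 8 members of the Wnt target and barrier list passed, or 1 adjusted over the list alone. Among vascular markers Col1a2, Col3a1 and Atp13a5 had differences of -0.61, -0.48 and -0.72. None of these passed, but adjusted over the list alone 2 of 2 fibroblast and 2 of 4 pericyte markers did. Of 4 endothelial markers 3 were positive, with a median of 0.0740, and 0 passed, or 1 adjusted over the list alone.

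Both models shared 11 higher and 11 lower genes, and no gene was called in opposite directions. Of the HAL calls 65 of 66 had the same sign in HEP, and of the HEP calls 49 of 49 in HAL. Calls were selected for a difference from the same Sham arrays that the other comparison uses, which favours the same sign. No value for unchanged groups was computed for called genes, so these counts are a description only. Over all genes tested 71.1% had the same sign, against 66.6% in simulated unchanged groups with the same controls and a median of 59.2% with the Sham arrays split, so part of this comes from the shared controls. The shared rises included Ptges, Adamts9, Slc1a1, Fam43a, Mt2A and Depp1, and the shared falls Lama4, Slc39a8, Atp10a, Gsta4, Mpdz and Tpm1, as well as Nr1d2, with the same limit on its direction. Independent lists, a figure that ignores the shared controls, would share 0.338 higher and 0.544 lower genes. Simulated unchanged groups against the same controls shared 0 in either direction, but without changed genes few calls can arise, so this 0 says little. No comparison had separate changes in each model against shared controls. How many of the shared genes the controls account for was thus not tested. With the Sham arrays split 4 and 4, and so with fewer controls in each fit, the median over 70 splits was 0 shared genes in either direction, with at most 1. Without HEP array 8 the models shared 57 genes, and with array weights 52. Across genes, which are not independent replicates, the differences correlated with r = 0.670, against 0.502 on average in 50 simulations of unchanged groups and 0.323 as the median with the Sham arrays split. The covariance was 0.0647, against 0.0268 simulated and 0.0399 with the Sham arrays split. The simulations drew the noise of each gene independently, without shifts of whole arrays, so real unchanged groups may vary more than the simulated ones.

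In the direct comparison of HAL with HEP limma called 0 of 1738 genes, with a smallest adjusted p = 0.245, and 161 genes had an unadjusted p under 0.05. Without HAL array 7, and in the corrected model-based reading, 1 gene was called. Camera called 0 lists. The list with the lowest adjusted p was the Wnt target and barrier programme (adjusted p = 0.128). It was called without HAL array 7 (adjusted p = 0.0283) and without HEP array 6 (adjusted p = 0.0389), and ranged up to 0.451 with other arrays left out, so whether its call in HAL differs between the models rests on single arrays.

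Of the 12 genes chosen beforehand for the barrier and its surroundings, Cldn5, Ocln, Tjp1, Abcb1a, Slc2a1, Glul, Vcam1 and Gfap each had a probe at 10 or above on all arrays of every group, and their changes were not read. Mmp9 and Icam1 had probes below 10 only. Slc7a5, a transporter of large neutral amino acids, had differences of -0.02 in HAL and 0.03 in HEP. Aqp4, the water channel of astrocyte endfeet, had differences of -0.14 in HAL and 0.06 in HEP. None of these passed, with adjusted p = 0.977 and 0.970 for Slc7a5 and 0.791 and 0.929 for Aqp4 in limma.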

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

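All tests of explanations in this part were chosen after the results were seen.

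The direction of the calls against Sham could be wrong if values just above 9 had lost a zero and were read at 10 or above. A smooth spread around such values would put as many cells into the readings just beside that range as into the cells of 8 digits. Over the 93 genes called in either model there were 0.189 neighbouring cells per cell of 8 digits (bootstrap interval 0.150 to 0.235), which argues against this as the whole source. The corrected model gave the same sign for 66 of 66 HAL calls and 49 of 49 HEP calls, and called 51 and 38 of them. It reads the same digits, starts from the main reading and favours 8 decimals over 9, so this agreement is no independent evidence.

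The 45 genes called lower in HAL had a median difference of -0.758. A shift of all readings on some arrays may produce such a set, since HAL arrays 2 and 5 and Sham array 3 had the lowest median readings, at 9.95, 9.99 and 9.999. After each array was centred on its median, 44 of the 45 were called lower, with a median of -0.703. The median difference over all genes was only -0.038, so centring could hardly end these calls. This argues only against a shift of the medians as the whole source of these falls. The excess of falls over rises did not stay, as 21 higher and 45 lower genes became 41 and 44 with centring. A shift may thus account for that excess. Without these 3 arrays the 45 had a median difference of -0.680 with a median SE of 0.190, against 0.176 for the SE with all arrays, and 20 of them were called lower. Most of the difference stayed, and calls ended with a smaller difference and a larger SE together. A lower share of vascular RNA in the HAL preparations cannot be told apart. The 11 vascular markers near 10 lay at a median of -0.200 relative to the 21 markers of other cells, with an interval of -0.957 to 0.0638. Few markers could be read, and the vascular ones diverged in HAL, from -0.87 for Col3a1 to 0.23 for Kcnj8. A first version of this test, on 5 junction genes with a median of 0.146, was replaced because the direction of that list was known when it was chosen. The surgery itself stays open as a biological explanation that the design names.

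Of the 6435 splits of the 16 arrays of a comparison into 8 and 8, 100 were run, the real one included. The share that reaches the real value can thus be no smaller than 1 of 100. The reading was chosen after calls under the real grouping were known, which may favour the real split. In both models the real split gave more than the others run, by a narrow margin for the lists, which argues against chance for the gene counts but does not exclude it. For HAL, 66 genes, 5 genes of at least 2-fold and 4 lists stood against at most 4, 2 and 3 in other splits, so that 1 of 100 splits, the real one, reached each value. For HEP, 49, 4 and 3 stood against at most 4, 2 and 2, again 1 of 100. For HAL against HEP the real split called 0 genes and 0 lists, which 100 of 100 splits reach by construction, so the splits decide nothing there. Other splits gave at most 2 genes and 1 list.

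Of 126 groups of readings 13 held an array far from the others. The format itself can give far readings, since a value below 10 that lost its last zero is read 1 too high. A chance rate of about 1 in 20 thus does not apply, and which readings arose this way was not tested. Sham array 3 had a median reading of 9.999. Among Sham arrays the far readings were 10.34 for Ptges, 10.46 for Adamts9, 9.95 for Stx3, 9.70 for Msl3l2 and 9.58 for Klf6. Among HAL arrays they were 10.12 for B4galt5, 10.39 for Gsta4 and 10.55 for Sesn2. Among HEP arrays they were 10.70 for Adgra2, 10.93 for Slc39a8, 10.99 for Rgs17 and 9.77 for Sesn2.

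Probes away from 10 were not used for the comparisons. In an exact permutation test of the decimals as angles, 12.2% of 28566 probes had a two-sided p under 0.05 for HAL against Sham and 9.65% for HEP against Sham. None passed an adjusted p of 0.05, but at the smallest possible p of 0.000155 a single probe could not pass over so many, so this says little. The corrected model, a directed reading, called 60 of 28572 such probes in HAL, 5 in HEP and 0 in HAL against HEP. It covers only integer parts in a limited range around 10, and its directions there were not tested on simulated data.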

How the results depend on the processing

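Alternatives from the table's reading onward were chosen after seeing the data: the other readings, the range of 3 to 12 cells, Fisher's test, shorter cells read with leading zeros and the removal of 3 arrays. Outside the faulty first version of the model, no named gene that was called, under the main or another setting, changed its sign. Other probes of a gene were not counted here, and 1 of Adamts9 had the other sign in HAL. The no-filter, strict-filter and loess alternatives were not run, because they need levels that the table does not hold. Where no value below shows the cause, the cause was not tested.

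Array weights gave 101 genes for HEP and 52 shared genes, and a fit of only the compared groups 32 for HEP. An estimated correlation left 0 lists in HAL and 0 in HEP, and fry, which does not compare a list with other genes, called 7, 6 and 3 lists for HAL, HEP and HAL against HEP. With shorter cells read with leading zeros there were 3 and 0 genes of at least 2-fold in HAL and HEP and 0 lists in HEP. The range of 3 to 12 cells of 9 digits gave 3 and 1 such genes, 32 genes in HEP, r = 0.716, 2 lists in HAL, 0 in HEP and 1 in HAL against HEP. Without the 3 arrays of the lowest medians HAL had 37 genes, 9 of at least 2-fold.

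Fisher's exact test of the number of cells under 9 digits, unread ones included, called 0 genes in HAL and 0 in HEP, with 224 and 197 at an unadjusted p under 0.05. At its smallest possible p of 0.000155 a single gene could not pass, but in HEP no gene reached that p. The corrected model called 96, 64 and 1 genes for HAL, HEP and HAL against HEP, 51 of the 66 HAL calls and 38 of the 49 HEP calls among them, with 3 and 0 of at least 2-fold and 0 lists in HEP. Its faulty first version called 59, 40 and 1, with 0 and 0 of at least 2-fold and 1 and 0 lists, and gave the other sign for 20 of the 66 HAL calls and 18 of the 49 HEP calls. In it 24 named differences changed sign. In HAL these were -0.18 for Slc1a1, -0.32 for Adamts9, -0.022 for Fam43a, -0.098 for Mt2A, -0.053 for Scn4b, -0.053 for Prxl2a, 0.13 for Slc39a8, 0.37 for Gpr155, 0.097 for Lama4, 0.031 for Rgs17, 0.092 for Stx3, 0.17 for Tdrp and 0.040 for Paqr5. In HEP they were -0.32 for Adamts9, -0.18 for Slc1a1, -0.11 for H4f3, -0.19 for Msl3l2, -0.033 for Wfdc1, -0.091 for Sesn2, -0.10 for Mt2A, 0.058 for Slc39a8, 0.40 for Cachd1, 0.030 for Arid1b and 0.082 for Lama4. The cause was its weights, since the corrected model changed no sign among the calls. The circular reading with zeros filled in called 18, 17, 4 and 0 probes for HAL and 1, 0, 2 and 1 for HEP at concentrations of at least 0, 0.4, 0.6 and 0.7, and with such cells missing 42, 10, 0 and 0 for HAL and 15, 2, 0 and 0 for HEP. The undirected exact test called 0 probes in each model, with the same smallest possible p.

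With the sample number as a block, 63, 41 and 0 genes were called for HAL, HEP and HAL against HEP. Same-numbered arrays had correlations of -0.0681 to 0.150, with 3 of 24 pairs over 0.1, so the numbers were not taken to pair the samples.

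With each array left out in turn, HAL gave 49 to 88 genes (4 to 8 of at least 2-fold, 1 to 5 lists), HEP 22 to 113 (0 to 5, 0 to 3 lists) and HAL against HEP 0 to 1 (0 to 1 list). Genes of at least 2-fold were 8 in HAL without HAL array 5, and in HEP 0 without Sham array 1, 2 without Sham array 4 or HEP array 3, and 1 without HEP array 4 or 7. Shared genes ran from 16 to 57 and r from 0.637 to 0.686. Over all settings, named genes kept their side of the threshold in 2293 values, lost their call in 230, gained one in 29 and reversed in 24. Signal over background could not be read, so what dim probes limit is unknown.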

Other observations

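Many members of several gene groups had no probe near 10, so that their changes were not read. Of 19 junction genes with a probe 14 had none near 10. A probe at 10 or above on all arrays was held by 11 of the 19, of which 2 had a further probe near 10, and by 11 of 27 blood-brain barrier transporters, 7 of 16 basement membrane genes, 6 of 12 heat shock genes and 10 of 23 oxidative phosphorylation genes. In contrast, 27 of 32 inflammatory genes, 20 of 22 cell cycle genes and 13 of 17 cholesterol synthesis genes lay below 10, with Ptgs2, which makes the substrate of Ptges, at 10 or above on all arrays of every group.

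Over the probes away from 10, the share in the top 5% of its own splits was 12.2% for the real split of HAL and Sham, with a median of 4.69% over all 6435 splits, and 2 splits, the real one included, reached it. For HEP against Sham 83 splits reached the real share of 9.67%, and for HAL against HEP 648 reached 6.56%.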
